A study of Drosophila melanogaster with 9 samples.

How the data were processed

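Whole embryos of 3 genotypes were profiled by RNA sequencing, with 3 libraries each for the Insc-Gal4 control, the Quad misexpression (ase, Kr, wor, SoxN) and the Hexa misexpression (these and hb, nub). Groups and library numbers were taken from the sample titles. The labels give HiSeq2500 sequencing with 150 bp reads. The aligner, counting software, genome build and annotation were not given in the sources used here, so no coordinates are reported. It is also not stated whether counting used strand or how reads of near-identical copies were assigned, so values of Hsp70, Attacin, GstD, drosomycin-like and histone genes are uncertain in that respect.

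The authors deposited 1 table of 10221 genes. Per the file headers it holds a raw read count per library, a linear RPKM and a log2 RPKM (reads scaled to transcript length and to the reads of the library). The 9 count columns and 9 log2 RPKM columns were used. The 9 linear RPKM columns were not used here, because headers of some controls name another driver. The log2 RPKM the authors deposited holds a floor of -10.86 where RPKM is 0, and these values were set to 0 after conversion to the linear scale. Rows were matched to gene names of the BDGP release 6.54 annotation (Ensembl 115), used only for the number and length of transcripts, chromosome arms and the order of neighbouring genes. Of the table's names 7707 were found there, 5123 of them among the tested genes.

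The deposited counts were compared with the deposited RPKM for each gene. In 5506 rows, 2483 of them tested, the count equalled RPKM times transcript length times 1 constant per library within 0.1% or 0.5 reads. It did so in 84.6% of 2447 tested genes with 1 annotated transcript and in 0.3% of 2676 tested genes with several. For many genes with several transcripts the count column holds only part of the reads behind the RPKM, and 275 tested genes, SoxN among them, have a count of 0 in all libraries with RPKM above 0. In every library the constants imply an RPKM denominator of several times as many reads as the count column sums to (8555639 to 11687961 reads).

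The test planned before the data were examined was edgeR's quasi-likelihood test on the counts. Because of this mismatch the main test became limma with a mean-variance trend and robust empirical Bayes moderation on log2(RPKM + 0.1), with all 9 libraries in 1 fit and the group as the only term. This change, the pseudocount and the filter were chosen after looking at the values in the table and before any test between groups. Genes with at least 0.5 RPKM in at least 3 libraries were tested (6190). No further scaling was applied to RPKM: the median shift of the tested genes was between -0.042 and 0.059 log2 per library. Calls are at a Benjamini-Hochberg adjusted p under 0.05. The planned edgeR test is kept as an alternative. Standard errors are those of the moderated fit, and errors of levels are SD over 3 libraries.

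Gene lists were fixed before the data were examined, and 26 with at least 3 tested members were tested with camera (limma), 2-sided, with a preset correlation of 0.01 between genes, on log2(RPKM + 0.1) rather than the planned log2 CPM, and adjusted over the lists. The misexpressed genes were left out of every list test. Many planned members had no row in the deposited table or were below the filter, and all counts are of tested members. Tested were 6 of 16 chitin and late epidermis genes and 20 of 29 neuropeptide genes. For blood cells and fat body 13 of 21 were tested, and for mitosis 32 of 36. No row was found for insc, pros and brat of the neuroblast list, nor for the landmarks dap, E2f1 and elav. A camera test asks whether a list stands apart from the other genes. No list was called when the correlation was estimated from the data, and the adjusted p of that version is given beside each call. Genes were named by a rule fixed beforehand: the 6 misexpressed genes, a set of landmark genes where the table holds them (dpn, mira, CycE, stg, repo), the 8 largest rises and falls per comparison (6 in Hexa against Quad), and up to 4 members with the smallest p from each list described. The largest changes had to pass the test, to have no overlap between the libraries of both groups, a symbol that is not only a CG or CR number and a mean of at least 5 in the higher group. That minimum was planned in CPM and applied in RPKM.

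Changes shared by Quad and Hexa were counted and set beside 100 draws in which all 9 libraries were simulated without group differences. Both simulated comparisons shared the simulated controls, and genes were drawn independently of each other. The tests were checked on simulated data with known changes, modelled on Quad against control. With 6190 genes, limma recovered 17.7% of genes changed 1.5-fold, 71.0% changed 2-fold and 97.1% changed 4-fold, and 10 of 137 calls (7.30%) were unchanged genes. edgeR on the 3167 genes with matching counts recovered 20.7%, 45.2% and 81.0%, with 5.83% of calls unchanged. A list of 20 genes raised 1.3-fold had an unadjusted camera p under 0.05 in 100 of 100 draws, and an unchanged list in 2 of 100. These genes were drawn independently, whereas the correlation estimated in the real lists reached 0.369 for mitosis and 0.827 for heat shock genes. The 2 rates therefore do not carry over to lists of correlated genes. Changes of 1.5-fold are thus mostly missed at this number of libraries.

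Alternatives fixed before the data were examined were other scalings and filters in edgeR, DESeq2 on the counts, a pseudocount of 1, no filter on low values, fits on the 2 groups compared, the library number as a block, leaving out each library in turn, and for lists an estimated correlation, fry and other scalings. Alternatives added after seeing the data were edgeR on matching counts only, RPKM divided by TMM factors, a minimum of 1 RPKM, leaving out Hexa 2 and 3, whose heat shock genes were highest, and the heat shock list mean as a covariate, for genes and for lists. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.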

Results

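RNA was sequenced from whole Drosophila melanogaster embryos, collected from stage 16 until the trachea filled with air, with more than 200 embryos per collection. By the sample titles each genotype carried the Insc-Gal4 driver, which uses the regulatory region of a gene active in neuroblasts (the neural stem cells of the fly). Headers of the linear RPKM columns of some controls name another driver, a conflict that was not resolved here. In the control the Insc-Gal4 driver stood over a wild-type OregonR chromosome set. In Quad embryos the driver acted on UAS transgenes of ase, Kr, wor and SoxN, and in Hexa embryos on these 4 together with hb and nub. The products of ase, wor and SoxN are transcription factors of early neuroblasts, and those of Kr, hb and nub act in the temporal sequence by which a neuroblast changes the progeny it makes. Each group had 3 libraries from separate biological samples, 9 in all. The labels place the control in experiment 1, Quad in experiment 2 and Hexa in experiment 3, whereas the series text speaks of 2 experiments, each with its own control. Only 3 control libraries are among the samples, so 1 misexpression group may have shared an experiment with them, and which one is not stated. No experiment in the labels held more than 1 group, so by the labels experiment and genotype cannot be told apart in any comparison. The control carried OregonR chromosomes in place of the UAS transgenes, and no group carried the transgenes without the driver. Differences in stock background can therefore not be told apart from the misexpression in comparisons with the control.

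Deposited counts summed to 11687961, 11674585 and 11338459 reads in the controls, 11465747, 10297721 and 10588280 in Quad and 8555639, 9083822 and 11390902 in Hexa. Act57B, a muscle actin, took 8.92 to 11.3% of the counts of a library. Levels are the authors' RPKM, given as mean ± SD over n = 3 libraries. Fold changes are differences of log2(RPKM + 0.1), which understates the change of genes with low RPKM. Adjusted p-values come from limma over 6190 genes with Benjamini-Hochberg adjustment.

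The misexpressed genes were compared first. The level of wor was 2.88 ± 0.289 RPKM in the controls, 15.1 ± 3.71 in Quad and 18.2 ± 5.34 in Hexa, a rise by log2 2.32 ± 0.241 (SE) in Quad (adjusted p = 6.28e-04) and by 2.58 in Hexa (adjusted p = 1.68e-04). The level of ase rose from 2.40 ± 0.0492 RPKM to 4.95 ± 0.438 in Quad (log2 1.01 ± 0.143, adjusted p = 0.00392) and 5.97 ± 0.883 in Hexa (log2 1.27, adjusted p = 4.58e-04). SoxN stood at 21.8 ± 2.60 RPKM in the controls, 38.1 ± 0.485 in Quad and 26.1 ± 5.12 in Hexa. Its rise in Quad (log2 0.81 ± 0.155, adjusted p = 0.0187) was lost without control 1, control 3 or any 1 of the Quad libraries, where the adjusted p reached 0.0801. SoxN in Hexa did not differ from the control past the threshold (adjusted p = 0.218), and without Hexa 2 it did (adjusted p = 0.040). It was lower in Hexa than in Quad (log2 -0.56, adjusted p = 0.0332), but not without any 1 of the Quad libraries, Hexa 1 or Hexa 2 (adjusted p up to 0.0927). Kr was not higher in either misexpression: it stood at 7.24 ± 0.845 RPKM in the controls, 6.07 ± 0.658 in Quad (log2 -0.25, adjusted p = 0.384) and 4.87 ± 0.608 in Hexa. The Hexa value was below the control (log2 -0.56 ± 0.145, adjusted p = 0.0213), a call lost without Hexa 1 or Hexa 2 (adjusted p up to 0.0639).

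Of the genes that belong to Hexa alone, hb had 1.56 ± 0.158 RPKM in the controls and 13.9 ± 4.69 in Hexa, a rise by log2 3.02 ± 0.443 (adjusted p = 0.00212). In Quad, which carries no hb transgene by its label, hb had 6.99, 2.83 and 1.81 RPKM in libraries 1, 2 and 3, and the difference from the control did not pass (log2 1.05 ± 0.443, adjusted p = 0.237). hb was higher in Hexa than in Quad (log2 1.98, adjusted p = 0.0186), but not without Quad 2, Quad 3 or Hexa 1, where the adjusted p reached 0.0616. The level of nub was 18.4 ± 0.46 RPKM in the controls, 20.6 ± 0.9 in Quad (adjusted p = 0.538) and 27.5 ± 4.77 in Hexa (log2 0.56 ± 0.133, adjusted p = 0.0154). Without Hexa 1 the nub call in Hexa was lost (adjusted p = 0.0525). The deposited counts, which hold only part of the reads of these 2 genes, did not rise: hb had 133, 149 and 125 reads in the controls and 78, 58 and 154 in Hexa, and nub 372, 573 and 378 against 148, 51 and 320. Transgene transcripts without the annotated untranslated regions would be undercounted in RPKM, which was not tested here.

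**Figure D1:**
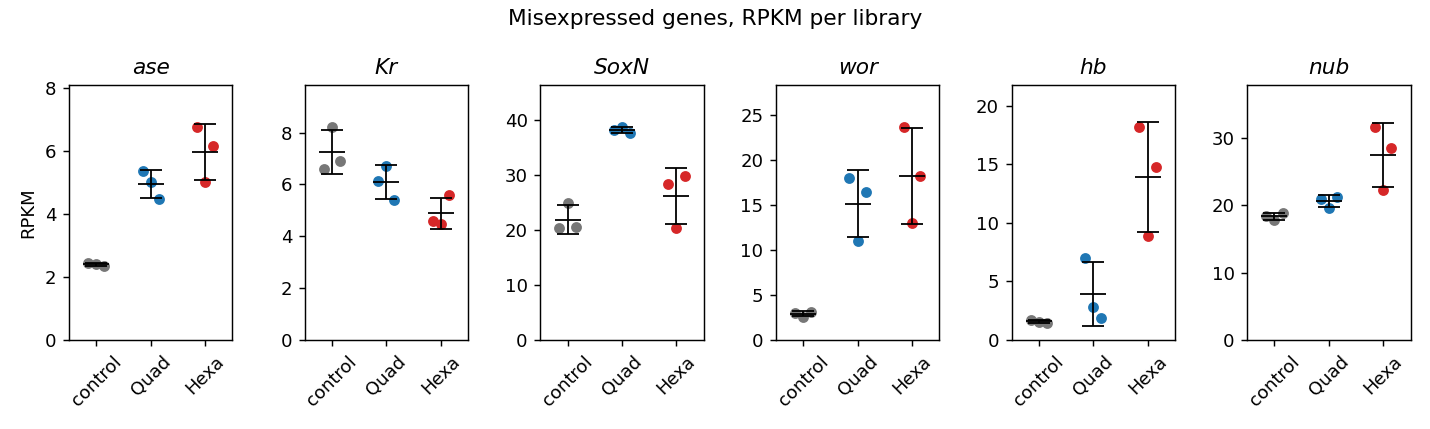
RPKM of the 6 misexpressed genes in each of the 9 libraries (points), with the mean and SD of each group of 3 (horizontal bar and whiskers). The 3 Quad and 3 Hexa libraries lie above the 3 controls for wor and ase, and hb reaches 6.99 RPKM in Quad 1 against 8.87 to 18.1 in Hexa.

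Quad was compared with the control to find what differed in embryos of the 4-gene misexpression. Drsl6, a drosomycin-like peptide gene, went from 0.0758 to 43.0 ± 14.7 RPKM (log2 7.90 ± 0.312, adjusted p = 1.25e-06). PGRP-SB2, a peptidoglycan recognition protein gene, went from 0.0796 to 13.3 ± 7.05 RPKM (log2 6.12 ± 0.363, adjusted p = 1.47e-05), and the glutathione S-transferase gene GstD7 from 4.71 ± 1.57 to 279 ± 69.2 RPKM (log2 5.88 ± 0.307, adjusted p = 6.51e-06). The metallothionein gene MtnB (log2 4.32, 8.13 against 0.409 RPKM), lcs (log2 4.22, 37.4 against 2.15 RPKM) and the odorant-binding protein gene Obp56g (log2 3.04, 7.43 against 0.801 RPKM) also rose. GstD6, a close relative of GstD7 with which it can share reads, rose by log2 4.21 (adjusted p = 0.0308), a call lost in edgeR, in the fit of the 2 groups and without control 1, control 3 or any 1 of the Quad libraries (adjusted p up to 0.114).

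The largest falls were smaller. Expression of thetaTry, a trypsin-like protease gene, fell to 2.08 RPKM from 7.75 (log2 -1.80 ± 0.298, adjusted p = 0.00883), and that of the Tweedle cuticle protein gene TwdlX to 35.6 from 99.0 RPKM (log2 -1.51 ± 0.245, adjusted p = 0.00785). The DNA repair gene mre11 (log2 -1.38), MFS1 (log2 -1.27), goe (log2 -1.26), CHKov1 (log2 -1.21) and CREG (log2 -1.12) fell with adjusted p between 0.00105 and 0.00517. The drosomycin-like gene Drsl5 fell by 2.03 on the log2 scale (adjusted p = 0.0368), which was lost without control 1, control 3 or any 1 of the Quad libraries (adjusted p up to 0.134).

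Among lists of genes fixed before the data were examined, 9 neuroblast factors other than the misexpressed genes were tested in Quad. Of these 2 rose, none fell, and 6 rose when adjusted over the list alone. The list stood higher by camera (median log2 0.41, adjusted p = 4.36e-04), but not with an estimated correlation (adjusted p = 0.932). Both risen members, nerfin-1 (log2 0.64, adjusted p = 0.0356) and klu (log2 0.48, adjusted p = 0.0466), were lost without control 1, control 3 or any 1 of the Quad libraries, and nerfin-1 also without control 2 (adjusted p up to 0.136 and 0.180). Neither passed with TMM factors on RPKM or without the filter on low values, and klu did not pass with the mean of the heat shock list as a covariate (adjusted p = 0.0607). The neuroblast markers dpn (5.51 against 4.47 RPKM, adjusted p = 0.246) and mira (16.0 against 12.3 RPKM, adjusted p = 0.160) did not pass, nor did CycE (adjusted p = 0.357), stg (adjusted p = 0.309) or the glial gene repo (adjusted p = 0.289).

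Of 32 genes of G2 phase and mitosis in Quad, 31 had a positive fold change and 1 rose, over all genes and adjusted over the list alone. The list stood higher by camera (median log2 0.37, adjusted p = 1.70e-05), but not with an estimated correlation (adjusted p = 0.932). The risen gene was the kinesin gene pav (2.52 against 1.44 RPKM, log2 0.77, adjusted p = 0.0362), a call lost without any 1 of the 6 libraries (adjusted p up to 0.136). Of 31 digestive genes of the midgut, 2 fell and none rose, with the same 2 adjusted over the list alone. This list stood lower by camera (adjusted p = 0.0108), but not with an estimated correlation (adjusted p = 0.932), nor without control 2 (adjusted p = 0.393) or Quad 1 (adjusted p = 0.139). The fallen members were the proteases thetaTry and Jon65Aiv (log2 -0.89, adjusted p = 0.0367), and Jon65Aiv was lost without any 1 of the 6 libraries (adjusted p up to 0.150). Of 55 cuticle protein genes 3 fell and none rose, or 6 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.0709). TwdlY fell with TwdlX (log2 -1.08, adjusted p = 0.0123; lost without control 3, Quad 2 or Quad 3, adjusted p up to 0.0579), as did Cpr72Ec (log2 -1.34, adjusted p = 0.0134; lost without control 3, adjusted p = 0.0561). The other 22 lists were not called in Quad.

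In all, 134 genes were higher and 156 lower in Quad, 290 of 6190, and 91 and 74 of these changed at least 2-fold. Dividing RPKM by TMM factors gave 130 higher and 223 lower, and edgeR with total counts as the scaling 118 and 87, so the balance depends on the scaling. The number fell to 182 without control 1, 143 without control 3 and 132, 162 and 167 without Quad 1, 2 and 3. On the counts as deposited edgeR called 231, of which 167 were shared in direction with the 290.

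Hexa was compared with the control to find what differed in embryos of the 6-gene misexpression. PGRP-SB2 rose to 75.3 ± 22.2 RPKM from 0.0796 (log2 8.70 ± 0.363, adjusted p = 1.41e-06) and Tsf1, which encodes the iron carrier transferrin, to 108 ± 31.9 from 0.165 ± 0.0166 RPKM (log2 8.64 ± 0.195, adjusted p = 1.85e-08). The call of Tsf1 rests on RPKM alone, since its deposited count was 0 in 8 libraries and 3 in Hexa 3. Over all 9 libraries the count column also held 0 reads of SoxN, CREG, Ppn and robo2, 2 of goe and 8 of Pif1B. It held 5 reads of Dro, 13 of Proc, 24 of srp and 51 of MtnB. For goe and srp the direction of these counts in Hexa against control was opposite to that of RPKM. The genes lcs (361 against 2.15 RPKM, log2 7.50), Drsl6 (16.3 RPKM, log2 6.50), MtnB (32.4 RPKM, log2 6.27), ng3 (6.32 RPKM, log2 5.62), lectin-37Db (148 against 3.34 RPKM, log2 5.40) and the antibacterial peptide gene AttA (13.3 against 0.266 RPKM, log2 5.20) followed, with adjusted p between 6.64e-07 and 0.00226. AttA and AttB are near-identical copies that can share reads.

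The largest falls in Hexa were in goe (8.09 ± 1.22 against 29.8 ± 2.44 RPKM, log2 -1.88 ± 0.172, adjusted p = 1.53e-04), TwdlX (31.7 against 99.0 RPKM, log2 -1.63, adjusted p = 0.00194) and snoRNA,Me28S-A1322 (log2 -2.12, adjusted p = 0.00706). Pif1B (log2 -1.36), dati (log2 -1.29), FucTC (log2 -1.28), CheB42c (log2 -1.26) and lov (log2 -1.26) fell with adjusted p between 2.37e-04 and 0.0102. Of the neuroblast landmarks, mira rose to 19.3 from 12.3 RPKM (log2 0.66 ± 0.140, adjusted p = 0.0101) and dpn to 6.52 from 4.47 RPKM (log2 0.53 ± 0.130, adjusted p = 0.0176), the latter not without control 1 (adjusted p = 0.0550). CycE (adjusted p = 0.766), stg (adjusted p = 0.189) and repo (adjusted p = 0.386) did not pass.

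Heat shock genes differed between the Hexa libraries. The mean of the 17 heat shock genes on the log2 scale, relative to the control mean, was 0.82, 2.17 and 2.52 in Hexa 1, 2 and 3, against -0.59 to 0.37 in the controls and -0.80 to 0.74 in Quad. In Hexa 10 of the 17 rose and none fell, or 13 adjusted over the list alone, and the list stood higher (adjusted p = 4.60e-04; adjusted p = 0.594 with an estimated correlation). The call ended with Hexa 1 as the only Hexa library (adjusted p = 0.157). Hsp70Bb, 1 of several near-identical copies of the main heat-inducible chaperone gene, had 512 ± 217 RPKM in Hexa and 67.4 ± 25.4 in the controls (log2 2.89 ± 0.502, adjusted p = 0.00512).

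Genes of G2 phase and mitosis rose in Hexa, 20 of 32 with none lower, or 22 adjusted over the list alone, in libraries that carried those heat shock means of 0.82, 2.17 and 2.52. The median rise was log2 0.69 (camera adjusted p = 1.00e-06; adjusted p = 0.594 with an estimated correlation). Examples were Det (7.0 against 2.62 RPKM, log2 1.39, adjusted p = 6.56e-04), the chromosomal passenger genes aurB (6.05 against 2.30 RPKM, log2 1.35, adjusted p = 0.00138) and Incenp (log2 1.01, adjusted p = 0.00272), and the cytokinesis gene tum (log2 0.99, adjusted p = 0.00316). With the heat shock mean of each library as a covariate 2 of the 20 calls were left, at a median of log2 0.56 and with the median SE up from 0.191 to 0.310. Of 20 genes of G1/S phase and DNA replication 3 rose and 3 fell in Hexa, or 1 and 1 adjusted over the list alone. That replication list did not pass (median log2 0.14, camera adjusted p = 0.942). Of 47 replication-dependent histone genes, near-identical copies whose reads can be shared, 14 rose and none fell, the same number adjusted over the list alone. The histone list stood higher (adjusted p = 0.00274), but not with an estimated correlation (adjusted p = 0.594) or with the heat shock covariate (adjusted p = 0.101). With the covariate 0 of the 14 calls were left, while the median went from log2 0.68 to 0.74 with 37 of 47 positive, and the median SE from 0.330 to 0.524. Of 9 neuroblast factors 5 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.0966). With the covariate 0 of these 6 calls were left, the median went from log2 0.51 to 0.36 with 7 of 9 positive, and the median SE rose from 0.140 to 0.213. The largest of these rises was in insb (7.85 against 3.26 RPKM, log2 1.27, adjusted p = 0.00356).

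Neuropeptide genes rose in Hexa in 12 of 20 cases and none fell, or 15 and 1 adjusted over the list alone, beside the same heat shock means. The list stood higher by camera (median log2 0.58, adjusted p = 0.00259), but not with an estimated correlation (adjusted p = 0.594). With the heat shock covariate the list was still called at the preset correlation (camera adjusted p = 0.00225), with a median of log2 0.73. The median SE went from 0.190 to 0.300, and 3 of the 12 calls were left. Among the 12 were the insulin-like peptide gene Ilp7 (1.59 against 0.454 RPKM, log2 1.66, adjusted p = 0.00289) and the adipokinetic hormone gene Akh (13.2 against 5.80 RPKM, log2 1.12, adjusted p = 0.00541). Proc (23.7 against 13.2 RPKM, log2 0.85, adjusted p = 0.0116) and the myosuppressin gene Ms (log2 0.77, adjusted p = 0.0118) also belonged to the 12. Of 12 genes of neurotransmission 5 rose and none fell, or 7 and 1 adjusted over the list alone, without a call for the list (adjusted p = 0.0907). Trh, the tryptophan hydroxylase of neurons that make serotonin, rose to 9.56 from 4.31 RPKM (log2 1.12, adjusted p = 0.00251).

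Genes of blood cells and fat body fell in Hexa, 9 of 13 with none higher, or 11 and 1 adjusted over the list alone, again beside heat shock means of 0.82, 2.17 and 2.52. The list stood lower (median log2 -0.51, adjusted p = 5.78e-04), but not with an estimated correlation (adjusted p = 0.594) or on the log2 CPM of the deposited counts (adjusted p = 0.204). The count column held 0 reads of Ppn, 24 of srp and 107 of Pxn over all 9 libraries. Genes with too few reads were left out of the log2 CPM test, so it did not cover all members tested on RPKM. The matrix protein gene Ppn (85.2 against 152 RPKM, log2 -0.85, adjusted p = 0.00734), the peroxidasin gene Pxn (log2 -0.76, adjusted p = 0.0120), the prophenoloxidase gene PPO1 (log2 -0.74, adjusted p = 0.0123) and the GATA factor gene srp (log2 -0.51, adjusted p = 0.0168) were lower. Of 6 genes of chitin and the late epidermis 3 fell and none rose, the same number adjusted over the list alone (adjusted p = 0.0207; adjusted p = 0.594 with an estimated correlation). The 3 were laccase2, Cht7 and knk (log2 -0.75, -0.54 and -0.71), each lost without control 1 and knk also without Hexa 1 (adjusted p up to 0.0587).

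Of 13 immune genes 6 rose and 1 fell in Hexa, or 6 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.183). AttB (19.6 against 0.742 RPKM, log2 4.60, adjusted p = 6.45e-04) and Dro (log2 3.34, adjusted p = 0.00301) rose with AttA. Of 31 midgut genes 7 rose and 5 fell, the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.942). The protease gene Jon74E (log2 4.0, adjusted p = 4.71e-04) and the amylase gene Amy-d (log2 2.74, adjusted p = 0.0010) were higher and the mannosidase gene LManV (log2 -0.72, adjusted p = 0.00394) was lower. The ribosomal protein list stood higher (median log2 0.41, adjusted p = 0.00987) although 2 of 31 rose and 1 fell, none adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.772), without control 2 (adjusted p = 0.120), on log2 CPM (adjusted p = 0.272) and with the heat shock covariate (adjusted p = 0.478). The muscle list stood lower with 2 of 11 genes down, none adjusted over the list alone (adjusted p = 0.0469). It was lost with an estimated correlation (adjusted p = 0.594) and without control 3, Hexa 1 or Hexa 3 (adjusted p = 0.0580, 0.0764 and 0.127). It was also lost with TMM factors (adjusted p = 0.0506), with Hexa 1 alone (adjusted p = 0.0681) and with the heat shock covariate (adjusted p = 0.101).

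In all, 1184 genes were higher and 813 lower in Hexa, 1997 of 6190, and 488 and 109 of these changed at least 2-fold. Dividing RPKM by TMM factors gave 1042 higher and 1076 lower, so the share of rises among the calls depends on the scaling. The total was 925 when fitted on the Hexa and control libraries alone, 1033 by edgeR on the counts as deposited (833 shared in direction), 962 without control 1, 1002 without Hexa 1, 1250 without Hexa 2, 865 with Hexa 1 alone and 551 with the heat shock mean as a covariate. Of the genes named, Kr, dpn, mira, insb, Pif1B, Hsp70Bb, Pxn and srp did not pass with Hexa 1 alone, nor did Kr, nub, dpn, srp, laccase2, Cht7 and knk in the fit of Hexa and control alone. With the heat shock covariate Kr, hb, nub, dpn, mira, insb, snoRNA,Me28S-A1322, Pif1B, dati, CheB42c, Incenp, tum, Akh, Ppn, Pxn, srp, LManV, laccase2, Cht7 and knk did not pass.

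**Figure D2:**
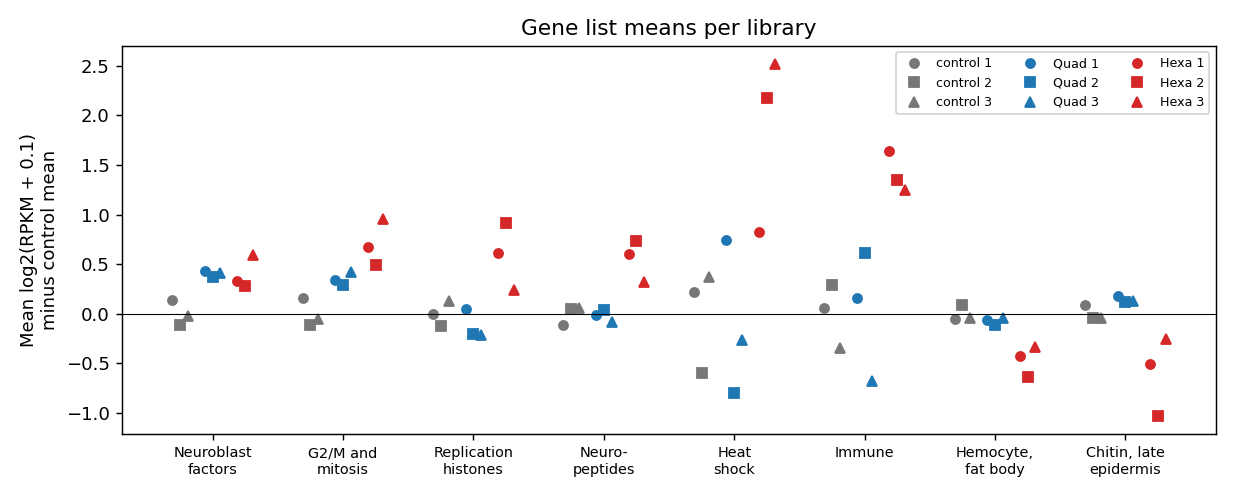
Mean of log2(RPKM + 0.1) over the tested genes of 8 lists in each of the 9 libraries, relative to the control mean (color gives the group and shape the library number). Mitosis genes lie above the controls in every Quad and Hexa library, and the heat shock mean spans 0.82 to 2.52 in Hexa.

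Hexa was compared with Quad to test directly what differed between the combinations, which by their labels differ in hb and nub. Tsf1 was at 108 ± 31.9 RPKM in Hexa and 1.01 ± 0.0356 in Quad (log2 6.57 ± 0.195, adjusted p = 2.42e-07). lectin-37Db (log2 4.46), Jon74E (16.0 against 0.707 RPKM, log2 4.28), AttA (log2 4.13), ng3 (log2 3.84) and AttB (19.6 against 1.5 RPKM, log2 3.79) were higher in Hexa with adjusted p between 1.16e-05 and 0.00926. AttA did not pass in edgeR without a low-count filter or with Hexa 1 alone. GstD7 was lower in Hexa than in Quad (35.0 ± 12.3 against 279 ± 69.2 RPKM, log2 -3.02 ± 0.307, adjusted p = 7.42e-04), as were Obp56g (log2 -2.05, adjusted p = 7.33e-04) and Pif1B (log2 -1.73, adjusted p = 0.00594). Drsl6 (log2 -1.41, adjusted p = 0.0164) was lost without Quad 3 (adjusted p = 0.0619). The axon guidance receptor gene robo2 (log2 -1.82, adjusted p = 0.0468) was lost in the fit of the 2 groups and without any 1 of the Quad libraries or Hexa 1 (adjusted p up to 0.127). GstD6 (log2 -2.79, adjusted p = 0.0477) was lost in edgeR apart from the fit of the 2 groups, and without any 1 of the 6 libraries (adjusted p up to 0.126).

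Neuropeptide genes were higher in Hexa than in Quad in 13 of 20 cases with none lower, or 14 adjusted over the list alone, in libraries with heat shock means of 0.82, 2.17 and 2.52 in Hexa against -0.80 to 0.74 in Quad. The list stood higher (median log2 0.65, adjusted p = 2.46e-04; adjusted p = 0.467 with an estimated correlation). FMRFa was 1 of them (2.64 against 1.31 RPKM, log2 0.95, adjusted p = 0.0120). The 17 heat shock genes had 10 higher and none lower, or 15 adjusted over the list alone (adjusted p = 5.36e-05; adjusted p = 0.544 with an estimated correlation, and 0.0515 with Hexa 1 alone). Of 47 histone genes 8 were higher and none lower, the same number adjusted over the list alone (adjusted p = 5.36e-05; adjusted p = 0.520 with an estimated correlation). Mitosis genes were higher in 6 of 32 cases and none lower, the same number adjusted over the list alone (median log2 0.43, adjusted p = 0.00852). That call was lost with an estimated correlation (adjusted p = 0.668), without Hexa 3 (adjusted p = 0.196) and with the heat shock covariate (adjusted p = 0.389). Det was higher (7.0 against 3.32 RPKM, log2 1.07, adjusted p = 0.00428), but not with that covariate (adjusted p = 0.0921). Of 9 neuroblast factors 1 was higher and 2 lower, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.615). Among the lower genes was klu (6.38 against 9.5 RPKM, log2 -0.57, adjusted p = 0.0104).

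Genes of blood cells and fat body were lower in Hexa than in Quad in 6 of 13 cases and none higher, or 8 and 1 adjusted over the list alone (median log2 -0.45, adjusted p = 5.69e-04). The call was lost with an estimated correlation (adjusted p = 0.467) and on log2 CPM (adjusted p = 0.229). The log2 CPM test left out genes with too few reads, and the count column held 0 reads of Ppn and 24 of srp over all 9 libraries. Ppn was at 85.2 against 164 RPKM (log2 -0.96, adjusted p = 0.00696). Genes of chitin and the late epidermis were lower in 4 of 6 cases and none higher, the same number adjusted over the list alone (adjusted p = 0.00219; adjusted p = 0.467 with an estimated correlation), Cht7 among them (95.3 against 158 RPKM, log2 -0.74, adjusted p = 0.00719). Of 11 genes of ecdysone synthesis and response 4 were lower and none higher, or 5 adjusted over the list alone (adjusted p = 0.0101). This call was lost with an estimated correlation (adjusted p = 0.467), on log2 CPM (adjusted p = 0.204) and with the heat shock covariate (adjusted p = 0.0569). The nuclear receptor gene ftz-f1 was lower at 84.1 against 145 RPKM (log2 -0.80, adjusted p = 0.0124). These falls too stand beside the higher heat shock means of the Hexa libraries.

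Of 13 immune genes 7 were higher in Hexa than in Quad and none lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.0414). The call was lost with an estimated correlation (adjusted p = 0.520) and without Quad 3, Hexa 1 or Hexa 3 (adjusted p = 0.0653, 0.0664 and 0.0774). Of 6 genes of sensory neurons 3 were lower, the same number adjusted over the list alone (adjusted p = 0.0314), and Root (4.91 against 8.58 RPKM, log2 -0.80, adjusted p = 0.00563) was 1 of them. The sensory call was lost with an estimated correlation (adjusted p = 0.467), without Quad 1 (adjusted p = 0.0641) and without Hexa 3 (adjusted p = 0.0776). Both lists missed the threshold with Hexa 1 alone (adjusted p = 0.0515). The ribosomal protein list stood higher with 2 of 31 up and none down, none adjusted over the list alone (median log2 0.46, adjusted p = 1.14e-04; adjusted p = 0.636 with an estimated correlation, and 0.128 with the heat shock covariate). Midgut genes were higher in 9 and lower in 3 of 31 cases, or 11 and 5 adjusted over the list alone, without a call (adjusted p = 0.0706), with Jon65Aiv (log2 1.5, adjusted p = 0.00206) and Amy-d (log2 2.61, adjusted p = 0.00245) among the higher ones.

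In all, 835 genes were higher and 596 lower in Hexa than in Quad, 1431 of 6190, and 355 and 92 of these differed at least 2-fold. edgeR on the counts as deposited called 686, of which 537 were shared in direction. Leaving out Quad 1, 2 or 3 gave 558, 574 and 442, leaving out Hexa 1 or 2 gave 560 and 643, and Hexa 1 alone gave 640. The balance also shifted, to 355 higher and 87 lower without Quad 3. With the heat shock covariate 337 were called, 310 higher and 27 lower. In that fit SoxN, hb, AttA, Drsl6, robo2, GstD6, Det, klu, FMRFa, Ppn, Cht7, ftz-f1 and Root did not pass. With Hexa 1 alone SoxN, hb, AttA, Pif1B, Drsl6 and GstD6 did not pass.

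The changes of Quad and Hexa against the shared controls were then set side by side. Of the genes called in both, 109 rose in both, 88 fell in both and 2 moved in opposite directions. PGRP-SB2, Drsl6, lcs, MtnB and wor were among the shared rises, and goe and TwdlX among the shared falls. Independent lists of these sizes would share 25.6 rises and 20.5 falls. The correlation of the fold changes across genes, which are not independent replicates, was 0.608. In 100 draws with all 9 libraries simulated without group differences and controls shared by both comparisons it was 0.501 on average. The share of genes with equal sign was 73.9% against 66.6%, and the covariance 0.328 against 0.0541, a difference of 0.274. The highest simulated covariance was 0.0657. Simulated genes varied independently, whereas the correlation estimated for the heat shock genes was 0.827. A shift of many genes together in the shared controls is therefore absent from the draws, and their range does not bound the excess. The 3 controls are too few to be split, so part of the excess over independent lists can come from sharing them. The 197 shared calls became 121 without control 1, 111 without control 3 and 105 when a 2-fold change was also required.

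**Figure D3:**
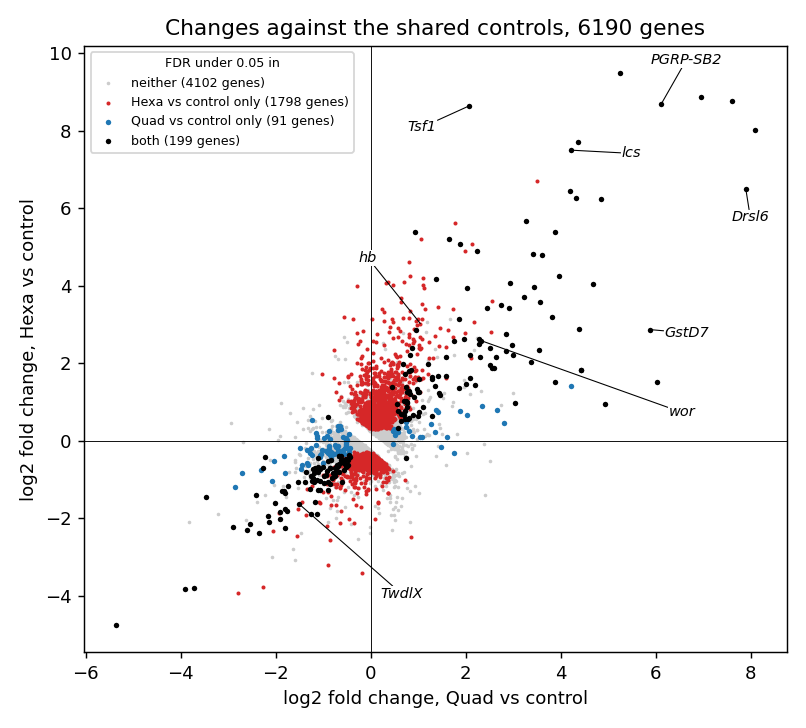
log2 fold change of 6190 genes in Quad (x axis) and Hexa (y axis), each against the same 3 controls, colored by where the adjusted p was under 0.05. Of these genes 199 passed in both comparisons, 91 in Quad alone and 1798 in Hexa alone, and Tsf1 and hb lie far above the x = y diagonal.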

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

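Alternatives chosen after seeing the data were edgeR on matching counts, TMM factors on RPKM, a minimum of 1 RPKM, Hexa 1 alone and the heat shock covariate; the others were planned. Fits on counts were not read for single genes whose counts do not match RPKM. Totals of calls on the counts as deposited and list tests on log2 CPM did include such genes where they had enough reads. Of 191 calls of named genes 83 were tested in every alternative and 28 of these were kept in each; 54 of the 191 were kept wherever tested, and none changed direction. The list of heat shock genes turned from higher to lower in Hexa with its own mean as the covariate, which the covariate brings about (adjusted p = 0.547 against control and 0.650 against Quad). The balance of calls turned in some settings: TMM factors gave 1042 higher and 1076 lower in Hexa vs control, and DESeq2 507 and 532 in Hexa vs Quad. The cause of the changes in number was not tested, except that leaving out libraries or fitting fewer of them leaves fewer residual degrees of freedom.

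Quad vs control (290 calls) ranged from 132 to 331 when a library was left out, and the other settings gave 205 to 383 apart from 172 in edgeR with a replicate block. With 134 higher and 156 lower in the limma test, edgeR called 118 and 113, or 118 and 87 with total counts as the scaling, and TMM factors on RPKM gave 130 and 223. Hexa vs control (1997) ranged from 962 to 2199 when a library was left out. It was 925 in the fit of the 2 groups, 551 with the heat shock covariate and 865 with Hexa 1 alone, where that library is assumed to vary like the other groups. In edgeR it was 1033 with TMM, 1029 with RLE, 921 with total counts, 949 without a filter, 1047 with a minimum of 1 CPM, 547 in the 2 groups, 798 with a replicate block and 828 on matching counts; DESeq2 gave 1409. Hexa vs Quad (1431) ranged from 442 to 1840 when a library was left out, was 640 with Hexa 1 alone and 337 with the heat shock covariate, and in edgeR 686, 681, 534, 637, 690, 695, 435 and 458 in the same order; DESeq2 gave 1039. The shared calls (197) ranged from 111 to 217 without a control and were 105 with a 2-fold minimum.

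Libraries of equal number correlated weakly: of 9 such pairs 2 were above 0.1 (range -0.152 to 0.179), and 5 of 9 libraries correlated best with their own number. Control and Quad libraries of equal number had r of 0.098, 0.179 and 0.147, above every control and Quad pair of unlike number (highest 0.048). Control and Hexa libraries of equal number had -0.152, -0.151 and -0.035. Pairing by library number is thus not excluded between control and Quad. With that number as a replicate block in limma the counts were 226, 1373 and 882, the list calls 3, 8 and 11 and the shared calls 161.

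Lists called were 3, 8 and 10 in Quad vs control, Hexa vs control and Hexa vs Quad. With an estimated correlation 0 passed in each by camera, with lowest unadjusted p of 0.0970, 0.0442 and 0.0662. For a change in a constant direction fry called 0, 15 and 12, and for a change in either direction 3, 24 and 20. Leaving out a library gave 2 to 5, 7 to 10 and 8 to 10, and the heat shock covariate 3, 5 and 8. RPKM scaled to total reads is what the authors deposited, so the planned scaling to totals was run on log2 CPM and gave 4, 6 and 9. At 3 libraries per group most simulated 1.5-fold changes went undetected, and depth was not varied.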

Other observations

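The heat shock, contamination, age and experiment tests and the counts of splits were chosen after the results were seen. The tests of gene position were chosen before their results. The readings of the chromosome arm test and of the age test were set after their values were seen. That of the test for a stretch of chromosome departs from the reading set beforehand.

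Single genes of other lists also passed in Hexa. The temporal factor gene pdm2, a neighbour and relative of nub, rose to 14.1 ± 3.53 RPKM from 7.27 ± 0.432 (log2 0.91, adjusted p = 0.00626), but 1 of the 3 temporal factors rose and 1 fell, and that list was not called (adjusted p = 0.919). The deposited counts of pdm2, which hold only part of the reads, were lower in Hexa (3.72 against 5.78 CPM). The segmentation genes ftz (0.637 against 0.0552 RPKM, log2 2.24, adjusted p = 0.00183) and hkb (5.46 against 2.83 RPKM, log2 0.93, adjusted p = 0.00490) were higher in Hexa, the 2 of 10 tested segmentation genes to pass, and that list was not called (adjusted p = 0.153). roX2, a noncoding RNA of dosage compensation in males, was higher in Hexa (10.9 against 6.12 RPKM, log2 0.83, adjusted p = 0.00806), 1 of 2 that rose among 4 genes of a list without a call (adjusted p = 0.0966). hkb and roX2 did not pass with Hexa 1 alone, nor ftz and hkb with the heat shock covariate.

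Genes chosen after their values were seen stood apart between all controls and all 6 misexpression libraries. The odorant receptor genes Or19a (1.06 to 2.12 RPKM) and Or19b (4.29 ± 0.522 RPKM) and Victoria (1.59 to 1.97 RPKM) were expressed in the controls. In the 6 misexpression libraries Or19a and Victoria stayed under 0.1 RPKM and Or19b at or under 0.117. CG10996 had 1.60 to 3.61 RPKM there and at most 0.0358 in the controls. The eye color gene w, a marker of many transgenes, did not stand apart (adjusted p = 0.715 in Quad and 0.300 in Hexa). It had 107, 41.8 and 117 RPKM in the controls, 87.0, 45.1 and 50.1 in Quad and 65.4, 134 and 280 in Hexa, and within each group its order was that of the heat shock means. The marker gene y did stand apart and was called higher in both Quad and Hexa. It had 34.1, 44.7 and 31.4 RPKM in the controls, 76.5, 63.3 and 78.6 in Quad and 66.9, 52.9 and 50.3 in Hexa. Why y was higher was not tested. The 2 genes called in opposite directions were CG42260 (log2 0.75 in Quad, -0.44 in Hexa, adjusted p = 0.00135 for the difference) and Jon65Aiv (log2 -0.89 and 0.61, adjusted p = 0.00206).

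The first pattern was the hb level of 6.99 RPKM in Quad 1, against 2.83 and 1.81 in Quad 2 and 3. To bring hb to that level, Hexa material would have to make up 40.3% of Quad 1. Over 25 genes at least 8 times higher in Hexa than in Quad 2 and 3, the median share of Hexa signal in Quad 1 was 1.36% (quartiles -0.895 to 17.3%), and 0 genes reached the share of hb, which argues against such a mixture. No biological explanation was tested, and a difference between the embryo collections of Quad stays open.

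The rise of mitosis genes in Hexa could come from the misexpression, from the heat shock response, from younger embryos or from the experiment that held each group. With the heat shock mean as a covariate the list kept its direction with an adjusted camera p of 0.00183. Its median log2 change went from 0.69 (quartiles 0.49 to 0.91) to 0.56 (0.38 to 0.75), and 2 members passed where 20 had, with 31 of 32 still positive; the median SE of a member rose from 0.191 to 0.310. At the preset correlation a linear adjustment for the heat shock mean thus did not remove the rise against control. Heat shock means were 0.82 to 2.52 in Hexa and -0.59 to 0.37 in the controls, without overlap. The adjustment therefore cannot exclude a heat shock effect tied to the group. Against Quad the same covariate ended the camera call of the mitosis list (adjusted p = 0.389), so for that difference heat shock stays open. Neuropeptide genes, which come on late in embryogenesis, were higher in 12 cases and lower in none, which younger embryos would not give. More of these rising than falling had been set to speak against age, but that bound was too narrow. Chitin genes were lower (camera adjusted p = 0.0207) and histone genes higher (camera adjusted p = 0.00274), as younger embryos would give. The chitin and histone list calls were lost with an estimated correlation (adjusted p = 0.594), as was that of the neuropeptides. The histone call was also lost with the heat shock covariate (adjusted p = 0.101). The segmentation genes ftz and hkb were higher too, but they were the only 2 of 10 to pass. Their list was not called (camera adjusted p = 0.153), and neither gene passed with the heat shock covariate. With that covariate the histone median went from log2 0.68 to 0.74 and the median SE from 0.330 to 0.524, so the loss of the histone call does not show a smaller rise. The values go both ways, so younger embryos stay open. In the labels 0 experiments held more than 1 group, and the series text does not say which experiment the 3 controls came from, so a difference between experiments cannot be told apart from the misexpression, which stays open as a hypothesis.

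The genes changed alike in Quad and Hexa could reflect the misexpression or stocks that differ in a stretch or arm of a chromosome. Of the 197 genes, 169 with a position formed 6 neighbouring pairs of opposite direction (random sets 2.76 on average, 95% at or under 6, permutation p = 0.0625) and 18 of equal direction (random mean 2.85, highest 11, permutation p = 0.0001, the smallest that 10000 draws can give). For opposite pairs, staying at or under the 95% value was set beforehand to speak against a stretch, and the 6 pairs met it. With so few such pairs in random sets, meeting that bound excludes nothing. Neighbours of equal direction include goe, TwdlX and TwdlY, but gene families in tandem give such pairs too. The pair of y and ase says nothing of a stretch, since ase is misexpressed and y is a marker gene used in stocks. The chi-square over chromosome arms was 6.99, between the random mean of 4.01 and the 95% value of 9.44 (permutation p = 0.138); staying under that value was set beforehand to speak against an arm, but a value above the random mean in so few genes excludes nothing. Neither explanation can therefore be told apart from a shared effect of the transgenes. Or19a, Or19b and Victoria, near absent in all misexpression libraries, and CG10996, near absent in all controls, could likewise reflect stocks or misexpression. They were chosen after their values were seen, and no test here separates these sources.

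With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 2 groups compared, the real split called 310 genes in Quad vs control, 925 in Hexa vs control and 1537 in Hexa vs Quad. The highest of the other splits called 1, 0 and 1. In each comparison 1 split, the real one, called as many genes. Every other split mixes libraries of both groups, so a difference between the groups, whatever its source, enters its residual spread and lowers its calls. The contrast therefore does not measure how many calls an arbitrary grouping would give.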
